A study of Mus musculus with 12 samples.

How the data were processed

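Left ventricular myocardium of wild-type C57Bl6J/129X1 hybrid mice infused for 3 days with NaCl or AngII/PE was profiled as 12 RNA-seq libraries, 3 for each combination of treatment and sex. RNA was purified with a PureLink column kit, per the labels' protocols. The mapping of libraries to groups was taken from the labels, which number no replicates and name no batch. The labels do not say that each library came from a separate mouse.

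Per the submitters' processing notes, cutadapt, STAR 2.4.2a, Subread, featureCounts and DESeq2 were used by the authors with mouse genome build mm10; their roles, order, settings and annotation are not given in the sources used here. The values analysed are those of a single table of the authors' own comparison of treated with control libraries. Per the file headers, it gives a gene symbol, an average log2 fold change and a p-value adjusted by the authors to control the false discovery rate. What was averaged, the model and its covariates, the number of genes tested and the rule by which genes were listed are not given in the sources used here, and no standard error or unadjusted p-value accompanies the deposited values. Because the table holds only listed genes, a gene without a value is described as having no value analysed here, which does not mean that it did not change. Values per library were not analysed here (columns of such values used: 0), so the depth, and the precision it would give, is unknown, and no error or number of replicates can be set beside a value.

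How the table was made could affect the measurements in several ways. A selection that starts at different sizes for rises and falls changes the split of higher against lower genes. A scaling between libraries that is thrown off by a large rise of matrix transcripts would shift all fold changes together. An average of fold changes from separate sexes would behave differently from the fold change of pooled arms for genes expressed in a single sex. Whole tissue gives the sum over all its cells, so a changed mix of cells changes fold changes without any cell altering its transcripts. Unless strand was used in counting, which is not given in the sources used here, overlapping and antisense genes can share reads.

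The tests to be used were set before the data were examined, with a version for each kind of table. For a table of called genes only, the design was to count the listed genes in each direction at the authors' adjusted p threshold of 0.05 and to test each of 36 gene lists (798 genes, 480 with a value) by the direction of its listed members. The design also held count-based and log-scale models for values per library, tests within each sex, a treatment by sex interaction and a comparison of control females with control males; none of these was run. For each list, the numbers of higher and lower members were set against those of the other listed genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 31 lists with at least 5 listed members. A few genes stand in more than 1 list: Des, Rgs5, Tbx18 and Clu. Named genes were chosen by a rule also set before the data were examined. It took the 10 largest rises and 10 largest falls among symbols that are not predicted models, RIKEN clones or pseudogenes, up to 4 listed members with the largest absolute log2 fold change from each list that passed, and Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Col1a1, Col3a1 and Postn; no mean level was required because the table gives none. Further members of the lists named in the report, and the sex-linked and clock genes, were chosen after their values were seen, to describe the lists.

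The edges beyond which most listed rises and falls lie were estimated as the point where a flat density, set to that of the stretch just beyond, would hold as many genes as listed, with 95% intervals from 500 bootstrap draws. The 15 gene families of the closing section were defined by symbol after the data were examined and tested in the same way, adjusted over those 15. A few of the genes and families that were computed are not reported here. Positions and gene types come from GENCODE M21 on GRCm38 (the same assembly as mm10) by exact symbol: 3836 symbols matched a single gene, 8 matched several and 95 none. Of the matched genes, 3331 were protein coding. The table's column of gene descriptions was not used, because 146 symbols lack a description and 15 descriptions are given to 2 symbols each.

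The direction test was tested on simulated directions of the 3939 listed genes: over 50 draws with 10 lists planted at 95% higher, 95.8% of planted and 1.1% of unplanted lists were called. Each gene's direction was drawn independently, so these rates do not cover lists whose members vary together. On simulated fold changes with known offsets, 20 draws per offset, the midpoint of the edges was off by at most 0.0088. There, rises and falls were cut at the same size before the offset was added, so an uneven selection is not covered. Alternatives tried were an adjusted p threshold of 0.01, an absolute log2 fold change of at least 1, leaving out predicted models, RIKEN clones and pseudogenes (539 symbols), and, chosen after seeing the data, recentring on the midpoint of the edges with and without the size threshold. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.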

Results

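RNA sequencing was done on whole left ventricular myocardium from wild-type C57Bl6J/129X1 hybrid mice that had received NaCl (control) or AngII/PE for 3 days. AngII/PE is written as an abbreviation in the labels; in cardiac research it usually stands for angiotensin II, a vasoconstrictor peptide hormone, given with phenylephrine, an alpha-1 adrenergic agonist. The 12 libraries fall into 4 groups of 3, control females, control males, treated females and treated males, so that each of the 2 treatments is represented by 6 libraries with the sexes in equal numbers. The series title places the work in the setting of a mouse model of heart failure with preserved ejection fraction. The values analysed here are the authors' fold changes and adjusted p-values for 3939 listed genes in treated against control myocardium. Levels per library were not analysed here, so the depth of each library, the spread between mice and the responses of females and males on their own are unknown.

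The comparison of treated with control myocardium asks which transcripts changed in the left ventricle over 3 days of AngII/PE. Extracellular matrix transcripts had the largest median rise of the gene lists tested. Cthrc1, a secreted glycoprotein linked to collagen deposition, had a log2 fold change of 7.45, and Tnc, encoding tenascin-C, 7.17 in the authors' deposited table. Macrophage, cell cycle, interferon response, TGF-beta family and cytoskeleton genes were also higher. The natriuretic peptide transcripts Nppa and Nppb rose by 4.32 and 1.74 on the log2 scale in the authors' deposited table. Genes of fatty acid oxidation, the respiratory chain, the citrate cycle and branched-chain amino acid breakdown fell in nearly all listed cases, together with cardiac ion channels and adult contraction and calcium handling genes. Atp2a2, the sarcoplasmic reticulum calcium pump, changed by -0.96 and Myh6, the adult alpha myosin heavy chain of the mouse heart, by -0.65 on the log2 scale in the authors' deposited table.

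Of the 3939 listed genes, 2213 were higher and 1726 lower after AngII/PE, so 56.2% were higher. All had adjusted p-values below the 0.05 threshold, the highest being 0.0497 in the authors' deposited table. There, 3467 genes (88.0%) were under 0.001 and 16 were listed at exactly 0. Listed rises were larger than listed falls. The median log2 fold change in the authors' deposited table was 1.06 (2.08-fold) among the higher genes and -0.63 (1.55-fold) among the lower genes. A log2 fold change of at least 1 was listed for 1211 genes and of at most -1 for 274, and the split at 2 was 335 against 23. Most listed values lie beyond estimated edges of 0.59 for rises (95% interval 0.586 to 0.600) and -0.38 for falls (-0.385 to -0.369), and 11 genes, 8 higher and 3 lower, lie inside both by over 0.05. Uneven edges can come from an uneven selection or from an offset of all fold changes, which were not told apart. Either would bear on the split of higher against lower genes and on the medians of the listed rises and falls. The midpoint of these edges is 0.11. Subtracting it from each value changed the sign of Atf3 alone (0.09 as listed), giving 2212 higher and 1727 lower genes.

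**Figure D1:**
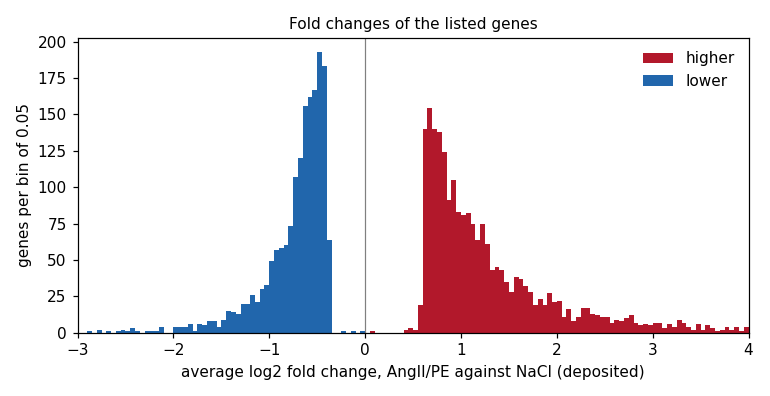
Distribution of the deposited average log2 fold change (horizontal axis, AngII/PE against NaCl) of the listed genes in bins of 0.05, with the number of genes per bin on the vertical axis, red for higher and blue for lower genes. Values between the edges at -0.38 and 0.59 are sparse, the higher genes reach further from 0 than the lower ones, and 34 genes above 4 and 4 genes below -3 lie outside the plotted range.

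The largest rise was that of Sprr1a, a small proline-rich protein induced by stress in heart muscle cells, with a log2 fold change of 9.60 (774-fold, adjusted p = 2.05e-124) in the authors' deposited table. It was followed there by C1qtnf3, a secreted C1q and TNF related protein, at 7.49 in the authors' deposited table. Next were the matrix genes Cthrc1, Tnc and Spp1, the last of which, encoding osteopontin, was at 6.71 in the authors' deposited table. Cdh3, encoding P-cadherin, followed at 6.44, Col11a1 at 6.41, Serpinb1c at 5.96, Cemip, a hyaluronan-degrading protein, at 5.86 and Postn, encoding periostin, at 5.68 in the authors' deposited table. Sprr1a lies at chromosome 3, 92483952 to 92485895, and Postn at chromosome 3, 54361109 to 54391037. Cthrc1 begins at chromosome 15, 39076932. All are protein coding genes in GENCODE M21 on GRCm38 (mm10).

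The largest falls were those of Sln and Myl7, at -5.30 (adjusted p = 1.15e-05) and -5.23 (adjusted p = 2.07e-05) in the authors' deposited table. Sln encodes sarcolipin, an inhibitor of the sarcoplasmic reticulum calcium pump, and Myl7 the atrial myosin light chain. Both are abundant in atrial muscle, as is Mybphl, which changed by -3.03 (adjusted p = 1.12e-10) in the authors' deposited table. Of the 121 genes with an absolute log2 fold change of 3 or more, ranked from the smallest adjusted p to the largest, these were number 116 (Mybphl), 119 (Sln) and 120 (Myl7). The other large falls were those of Aqp6 (-3.22, adjusted p = 0.0414), the skeletal muscle type chloride channel gene Clcn1 (-2.90), and the mitochondrial ribosomal RNA mt-Rnr1 (-2.77) in the authors' deposited table. After them came Penk, encoding proenkephalin (-2.77), Lingo3 (-2.69) and the potassium channel genes Kcna1 (-2.51) and Kcnv2 (-2.50) in the authors' deposited table. Sln lies at chromosome 9, 53850164 to 53854560 and Myl7 at chromosome 11, 5896637 to 5898782 in GRCm38.

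Matrix genes led the groups that rose. Of 53 genes of collagens and matrix, 50 were listed, all higher (median log2 fold change 2.65; adjusted p = 4.25e-12), and 3 had no value analysed here. The fibrillar collagens Col1a1, Col3a1 and Col5a2 rose by 3.81, 3.17 and 3.44 on the log2 scale in the authors' deposited table. Basement membrane collagens rose less, with Col4a1 at 1.29 and Col4a2 at 1.05 in the authors' deposited table. The collagen cross-linking enzyme gene Lox was at 5.36 and Fn1, encoding fibronectin, at 3.91 in the authors' deposited table. Col1a1 occupies chromosome 11, 94936224 to 94953042 and Col3a1 chromosome 1, 45311538 to 45349706 in GRCm38. Matrix proteases and their inhibitors were higher for 16 of the 17 listed genes (adjusted p = 0.00231). That call was lost at an absolute log2 fold change of at least 1 (0.416) and with recentring as well (0.156). Of all genes left in those settings, 81.5% and 72.9% were higher, which leaves a list that leans higher little room to differ. The metalloproteinase inhibitor Timp1 led at 5.44, before Adam12 at 3.73 and Adamts8 at 2.77 in the authors' deposited table. Timp4, the inhibitor known for its high level in the heart, was the exception at -1.33 in the authors' deposited table.

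TGF-beta family genes were higher in 19 of 19 listed genes (median log2 fold change 1.42, adjusted p = 7.11e-05). The call was lost at an absolute log2 fold change of at least 1 (adjusted p = 0.208) and with recentring as well (0.116). With 81.5% and 72.9% of all genes left in those settings higher, even a list without lower members can miss the threshold. Ltbp2, a latent TGF-beta binding protein, rose by 5.06, the stress cytokine gene Gdf15 by 3.23, the activin inhibitor gene Fstl3 by 2.95 and Ccn2, encoding connective tissue growth factor, by 2.80 on the log2 scale in the authors' deposited table. The ligand genes were Tgfb3 at 1.94, Tgfb2 at 1.82 and Tgfb1 at 0.77 in the authors' deposited table. Fibroblast and myofibroblast markers were split 10 higher and 2 lower and missed the threshold (adjusted p = 0.106). Ccn4 was at 3.59, Cnn1 at 3.57, Runx1 at 2.77 and Acta2 at 1.14, while Gsn was at -1.65 in the authors' deposited table. Epicardial and mesothelial markers had 4 listed genes, all higher, too few for the test. They included Krt18 at 4.86 and the retinoic acid synthesis enzyme gene Aldh1a2 at 3.17 in the authors' deposited table.

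Immune genes were higher too. Monocyte and macrophage markers were higher in 18 of 18 listed genes (median log2 fold change 1.65, adjusted p = 1.08e-04). That call was lost at an absolute log2 fold change of at least 1 (adjusted p = 0.109). At that size 81.5% of all genes left were higher, and 72.9% with recentring added. A list without lower members can therefore miss the threshold in those settings. Lgals3, encoding galectin-3, was at 3.40, Ms4a7 at 3.32, the monocyte chemokine receptor gene Ccr2 at 3.28 and Gpnmb at 3.21 in the authors' deposited table. Interferon response genes were higher in 18 of 18 as well (median 1.08; adjusted p = 1.08e-04), a call lost at that size threshold (adjusted p = 0.208) and with recentring added (0.156). They ran from Zbp1 at 2.48 and Oas1a at 1.64 to Ddx58 at 0.59 in the authors' deposited table. Cytokine and chemokine genes were higher in 11 of 12 listed genes (adjusted p = 0.0267). Of the 39 genes of that list, 27 had no value analysed here, among them Il6, Il1b and Tnf. Ccl8 was at 3.47, the monocyte attractant gene Ccl2 at 2.49 and the alarmin gene Il33 at 2.24, with Cxcl14 at -0.42 in the authors' deposited table. Genes of oxidative stress and NADPH oxidase, a list not limited to immune genes, were likewise higher in 11 of 12 listed genes (adjusted p = 0.0267). Of the 25 genes of that list, 13 had no value analysed here, among them Nqo1 and Gclc. Hmox1, encoding heme oxygenase, was at 2.26, Nox4 at 2.14 and Sod2, the mitochondrial superoxide dismutase gene, at -0.86 in the authors' deposited table. Without predicted gene models, RIKEN clones and pseudogenes these last lists both missed the threshold (adjusted p = 0.0534), as they did at an absolute log2 fold change of at least 1 (0.416 for both) and with recentring added (0.156 and 0.225). Neutrophil markers had 2 listed genes, Lcn2 at 2.56 and Csf3r at 1.71, and mast cell and platelet markers 1, Pf4 at 0.68, in the authors' deposited table. None of the 15 lymphocyte markers had a value analysed here.

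Cell cycle genes were higher in 40 of 41 listed genes (median log2 fold change 2.44; adjusted p = 1.58e-08). The spindle checkpoint kinase gene Bub1 was at 5.08, Ccnb1, encoding cyclin B1, at 3.71, Top2a at 3.30 and the proliferation marker Mki67 at 3.01, and Cenpf at -0.77 was the exception in the authors' deposited table. Cytoskeleton genes rose in 21 of 21 (adjusted p = 3.14e-05), a call lost at an absolute log2 fold change of at least 1 (0.157) and with recentring as well (0.0792). The list has no lower member, and 81.5% and 72.9% of all genes left in those settings were higher. The beta tubulin genes Tubb3 and Tubb2b were at 4.52 and 2.85, the intermediate filament genes Vim at 1.90 and Des at 1.79, and Myl9 at 2.34 in the authors' deposited table. Immediate early genes, transcription factors switched on within an hour of a stimulus, were higher in 7 of 7 listed genes (adjusted p = 0.0320). Of the 19 genes of that list, 12 had no value analysed here, among them Fos, Jun and Egr1. Egr3 was at 2.05, Egr2 at 1.81 and Myc at 1.55 in the authors' deposited table. That call was lost at an adjusted p threshold of 0.01 (adjusted p of the list 0.103), after recentring on the midpoint of the edges (0.187), and without predicted models, RIKEN clones and pseudogenes (0.0685).

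Stress-response cardiomyocyte genes were 11 higher and 2 lower, which missed the threshold (adjusted p = 0.0685). Nppa, encoding atrial natriuretic peptide, was at 4.32, Uchl1 at 2.60, and Acta1, the skeletal alpha actin gene that is expressed in fetal heart, at 2.44 in the authors' deposited table. Ankrd1 was at 2.01, Nppb, encoding brain natriuretic peptide, at 1.74 and Myh7, the fetal beta myosin heavy chain gene of the mouse, at 0.92 in the authors' deposited table. The 2 lower members were the atrial genes Myl7 and Mybphl. Nppa and Nppb are neighbours on chromosome 4, with lower coordinates of 148000722 and 147985788, and Myh7 and Myh6 are neighbours on chromosome 14, at 54970684 and 54941921 in GRCm38.

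Adult contraction and calcium handling genes were lower in 10 of 11 listed genes (median log2 fold change -0.91; adjusted p = 0.00378), and the other 14 genes of the list had no value analysed here. Hrc, a calcium-binding protein of the sarcoplasmic reticulum, was at -1.37, Myl2, the ventricular myosin light chain gene, at -1.17, Tnni3, encoding cardiac troponin I, at -1.07 and Pln, encoding phospholamban, at -0.91 in the authors' deposited table. Slc8a1, encoding the sodium-calcium exchanger, went the other way at 0.81 in the authors' deposited table. Cardiac ion channel genes were lower in 14 of 14 (adjusted p = 3.62e-05). The potassium channel subunit genes Kcnv2, Kcnj3 and Kcnip2 were at -2.50, -1.28 and -0.99 and the sodium channel subunit gene Scn4b at -2.42 in the authors' deposited table.

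Genes of energy metabolism were mostly lower. Fatty acid oxidation and uptake genes were lower in 32 of 33 listed genes (median log2 fold change -0.83; adjusted p = 5.73e-10). Acot1 was at -1.81, Hadh at -1.20, Acadm, the medium-chain acyl-CoA dehydrogenase gene, at -1.12 and Cd36, the fatty acid transporter gene, at -0.71 in the authors' deposited table. The member that rose was Angptl4, a secreted inhibitor of lipoprotein lipase, at 1.38 in the authors' deposited table. Nuclear genes of oxidative phosphorylation were lower in 38 of 38 (median -0.62; adjusted p = 5.94e-13). The heart and muscle isoform genes Cox7a1 (-1.40), Cox8b (-1.01) and Cox6a2 (-0.76) headed them in the authors' deposited table. Mitochondrially encoded genes were lower in 11 of 11 (median -0.68; adjusted p = 2.90e-04), from mt-Nd5 at -0.85 to mt-Atp6 at -0.48 in the authors' deposited table. Citrate cycle and pyruvate dehydrogenase genes were lower in 18 of 18 (median -0.58; adjusted p = 2.09e-06), and branched-chain amino acid breakdown genes in 14 of 14 (median -0.75; adjusted p = 3.62e-05). Idh2 was at -0.92, the branched-chain ketoacid dehydrogenase subunit genes Bckdha at -0.94 and Bckdhb at -0.93 and their activating phosphatase gene Ppm1k at -0.98 in the authors' deposited table. Glycolysis and glucose uptake genes were mixed, 8 higher and 5 lower (adjusted p = 0.811). The ubiquitous glucose transporter gene Slc2a1 was at 1.05 and the insulin-responsive Slc2a4 at -0.66 in the authors' deposited table. The platelet type phosphofructokinase gene Pfkp was at 1.56 and the muscle type Pfkm at -0.66 in the authors' deposited table.

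**Figure D2:**
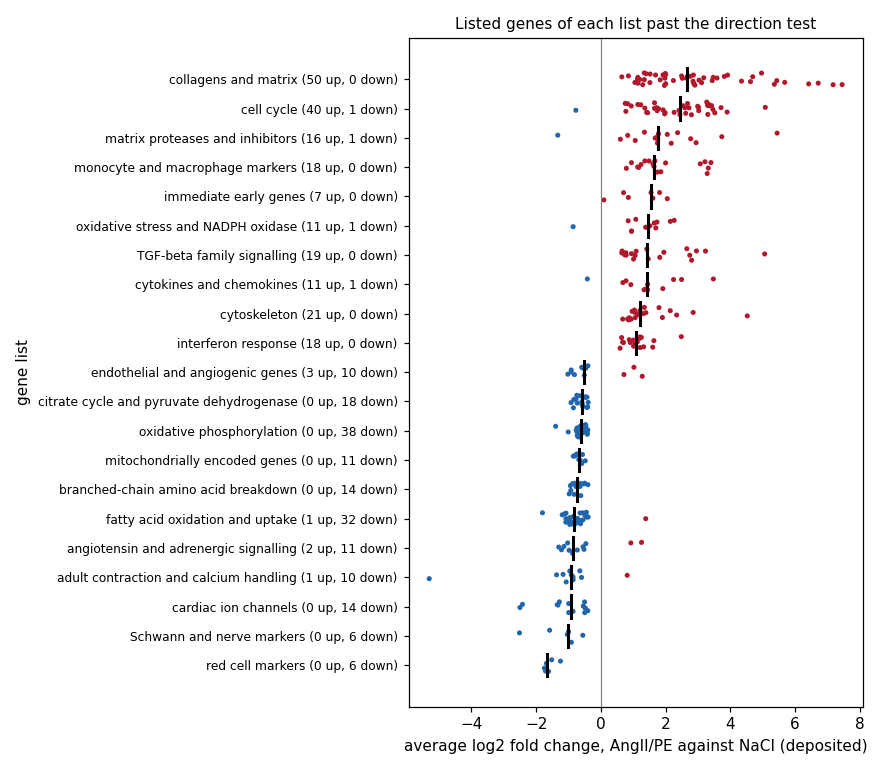
Deposited average log2 fold change (horizontal axis, AngII/PE against NaCl) of each listed gene in the 21 gene lists past the direction test, a list per line with its numbers of higher and lower genes; points are genes, red for higher and blue for lower, and black bars are medians. The 10 lists that lean higher have medians from 1.08 (interferon response) to 2.65 (collagens and matrix), and the 11 that lean lower from -0.53 (endothelial and angiogenic genes) to -1.65 (red cell markers).

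Receptors and enzymes of the infused pathways were mostly lower. Angiotensin and adrenergic signalling genes were lower in 11 of 13 listed genes (adjusted p = 0.00766). The alpha-1 receptor genes Adra1a and Adra1b were at -1.30 and -0.98 and the angiotensin receptor gene Agtr1a at -1.03 in the authors' deposited table. Ace, encoding the enzyme that makes angiotensin II, was higher at 1.25 and the receptor kinase gene Grk5 at 0.92 in the authors' deposited table. Endothelial and angiogenic genes were lower in 10 of 13 (adjusted p = 0.0331). Apln, encoding apelin, was at -1.02, Angpt1 at -0.92, Cldn5 at -0.92 and the VEGF receptor gene Kdr at -0.82 in the authors' deposited table. The inducible adhesion molecule genes Vcam1 and Sele were at 1.28 and 1.02 in the authors' deposited table. Smooth muscle and pericyte markers were 3 higher and 4 lower (adjusted p = 0.782), with Abcc9, a subunit of potassium channels gated by ATP that is not limited to vessels, at -1.17 in the authors' deposited table.

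Markers of other cells and tissues moved as well. Red cell markers were lower in 6 of 6 listed genes (adjusted p = 0.0128). The globin genes Hba-a2, Hbb-bs, Hba-a1 and Hbb-bt were at -1.75, -1.71, -1.68 and -1.62 in the authors' deposited table. Reads of these near-identical globin copies can be shared between them. Schwann and nerve markers were lower in 6 of 6 (adjusted p = 0.0128). Kcna1 was at -2.51, Gfra3 at -1.58 and Sox10, the glial transcription factor gene, at -1.04 in the authors' deposited table. Adipocyte markers had 2 listed genes, Car3 at -2.12 and Cfd at -1.93, in the authors' deposited table. Atrial and conduction markers were 4 higher and 4 lower (adjusted p = 0.787). Sbk3 was at -2.46 and Sbk2 at -2.28, Myl1 at 2.22 and Clu at 2.81 in the authors' deposited table.

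Sex-linked genes were listed although each treatment holds 3 female and 3 male libraries. Xist, the long noncoding RNA of the inactive X chromosome, was at 2.96 (adjusted p = 3.51e-04) in the authors' deposited table. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were at -0.37, -0.21, -0.14 and -0.01, and the largest of their adjusted p-values was 3.55e-07, in the authors' deposited table. As a list, sex-linked genes were 1 higher and 4 lower (adjusted p = 0.218).

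The remaining lists missed the threshold of the direction test. Unfolded protein response genes were 4 higher and 1 lower (adjusted p = 0.469), with 22 of 27 having no value analysed here. Heat shock chaperone genes were 4 higher and 2 lower (adjusted p = 0.782). The small chaperone gene Hspb1 was at 0.95 and the mitochondrial chaperone gene Hspd1 at -0.53 in the authors' deposited table. Genes of p53 and senescence were 6 higher and 1 lower (adjusted p = 0.187). Cdkn2b was at 2.27, Phlda3 at 1.45 and Gadd45a at -1.20 in the authors' deposited table. Circadian clock genes were 4 higher and 3 lower (adjusted p = 1). The activator genes Arntl and Npas2 were at -1.14 and -1.04 in the authors' deposited table. The repressor genes were mixed, with Per2 and Cry1 at 1.93 and 0.71 and Nr1d1 at -1.16 in the authors' deposited table.

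The list tests are two-sided Fisher's exact tests of higher against lower genes in a list and among the other listed genes, adjusted by Benjamini-Hochberg over the 31 lists with at least 5 listed genes, of which 21 passed. Several that passed had many members with no value analysed here. Among them were cardiac ion channels (11 of 25), TGF-beta family (13 of 32), angiotensin and adrenergic signalling (13 of 26) and endothelial genes (12 of 25). The tests compare directions among genes the authors listed and treat genes as independent, although members of a list vary together, so these p-values are too small by an unknown amount. Rises short of the edge of 0.59 were mostly not listed, while falls beyond -0.38 could be. Lists of small changes, such as the citrate cycle list (median -0.58) and the endothelial list (median -0.53), can therefore lean lower in part through the listing.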

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

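Tests that recentre the fold changes were chosen after seeing the data; the other settings were set before the data were examined. At an absolute log2 fold change of at least 1, the count of listed genes dropped to 1485 (1211 higher and 274 lower, 81.5% higher), and 6 lists passed the direction test in place of 21. With recentring on the midpoint of the edges as well, 1426 genes (1039 higher and 387 lower, 72.9% higher) and 9 lists were left. Fewer genes enter under these settings by construction, and several lists keep under 5 genes and are then not tested. The other genes are themselves mostly higher, so even a list without lower members can lose its call. Among the lists still tested, 7 and 6 lost their call and none turned its direction. The matrix proteases (adjusted p = 0.416 and 0.156), TGF-beta family (0.208 and 0.116), interferon response (0.208 and 0.156) and cytoskeleton lists (0.157 and 0.0792) lost it under both, and the macrophage list under the size threshold alone (0.109). An adjusted p threshold of 0.01 left 3738 genes (2115 higher and 1623 lower) and 20 lists, leaving out predicted models, RIKEN clones and pseudogenes 3400 genes (2028 and 1372, 59.6% higher) and 18 lists, and recentring alone 20 lists. Recentring alone changed the sign of Atf3 only, an immediate early gene, so it could hardly alter any other list. The immediate early list lost its call in each of these last settings (adjusted p 0.103, 0.0685 and 0.187); no list reversed among those still tested in a setting, 16 of 31 at the size threshold and 18 with recentring as well. The endothelial list, no longer tested at that size, kept Vcam1 (1.28) and Sele (1.02) as higher and Apln (-1.02) as lower genes in the authors' deposited table. Not run, for want of values per library or unadjusted p-values analysed here, were another normalization, other filters and pseudocounts, a model without a sex term, leaving out each library, a minimum mean level, Bonferroni adjustment, counts adjusted over the list alone, an estimated correlation within lists, other splits of the libraries and all tests between the sexes. No paired analysis was possible because the result comes from no test of libraries run here. Depth is unknown, so which listed genes rest on few reads cannot be said.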

Other observations

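The tests in this part were chosen after the results were seen, except the share of higher genes among the 196 other short protein coding genes, whose prediction was written before its result. Replication-dependent histone genes, transcribed during DNA synthesis, were higher in 31 of 32 listed genes (median log2 fold change 2.42; Fisher's exact test, adjusted p = 1.33e-06 over 15 families). H1f5 was at 3.88, H2ac4 at 3.63 and H2bc21 at -0.95 in the authors' deposited table. Kinesin motor genes were higher in 19 of 21 (adjusted p = 0.00335), led by the mitotic Kif14 at 3.34 and Kif2c at 3.26 in the authors' deposited table. Integrin genes, receptors for matrix proteins and for leukocyte adhesion, were higher in 14 of 16 (adjusted p = 0.0205). Itgax was at 2.89, Itgb1 at 1.20 and Itgb6 at -1.10 in the authors' deposited table. Serpin genes were higher in 10 of 10 (adjusted p = 0.00720), with Serpinb1a at 4.88 and Serpina3n at 3.07, and toll-like receptor genes, sensors of innate immunity, in 7 of 7 (adjusted p = 0.0345), with Tlr13 at 2.44 in the authors' deposited table. Mitochondrial ribosomal protein genes were lower in 23 of 23 (median -0.49; adjusted p = 3.95e-08). They ran from Mrps28 at -0.71 to Mrpl4 at -0.39 in the authors' deposited table. Rises as small as their median fall were mostly not listed (edge of the rises 0.59), so part of this lean can come from the listing. Genes of complex I and its assembly factors were lower in 38 of 38 (adjusted p = 2.87e-13), cytochrome c oxidase and ATP synthase genes each in 15 of 15 (adjusted p = 1.22e-05), and mitochondrial carrier genes in 11 of 15 (adjusted p = 0.0503). Annexin, potassium channel, Zfp and cytochrome P450 genes had adjusted p-values of 0.277, 0.313, 0.151 and 0.414. Histones and integrins are listed in families that overlap in function with the cell cycle and macrophage lists, and complex I genes with the oxidative phosphorylation list, so these are not separate lines of evidence.

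Several imprinted genes, expressed from a single parental copy, were listed. Along chromosome 12, 109541001 to 109749460 in GRCm38, Meg3 (1.67), Rtl1 (1.11), Rian (1.55), B830012L14Rik (1.52) and Mirg (1.10) were all higher in the authors' deposited table, whereas of all 139 listed genes on chromosome 12 only 57 (41.0%) were higher (Fisher's exact test, adjusted p = 0.00342 over 21 chromosomes). Elsewhere H19 was at 3.19, Mest at 1.10, Grb10 at 0.74 and Plagl1 at 0.65, and Cdkn1c, a cell cycle inhibitor, at -1.84 in the authors' deposited table. The ribosomal protein gene Rpl3 was at 1.05 and its striated muscle paralog Rpl3l at -1.69 in the authors' deposited table. Protein coding genes were higher in 59.4% of cases against 34.9% of the other listed genes matched to a single annotated gene (Fisher's exact test, adjusted p = 5.79e-24 over 12 gene types). Several other types leaned lower: long intergenic noncoding RNAs, 65 of 87 lower (adjusted p = 2.73e-08), antisense transcripts, 54 of 75 (3.21e-06), processed pseudogenes, 79 of 136 (0.00187), and unprocessed pseudogenes, 15 of 17 (7.43e-04). Processed transcripts, 21 higher and 25 lower (0.214), and transcribed processed pseudogenes, 5 higher and 2 lower (0.517), did not pass. Antisense transcripts and pseudogenes can share reads with their partner or parent genes. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 were at -2.77 and -2.37, with adjusted p-values of 0.00252 and 0.00601, in the authors' deposited table. These items were singled out after their values were seen.

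Sex-linked genes passed the threshold although the sexes are balanced in the labels. A larger share of female libraries in the treated arm, with fold changes of pooled arms, would need the control arm to be at most 3.21% female to give both the rise of Xist (2.96) and the fall of a Y-linked gene, where the labels give 50%, which argues against it. This calculation used the genes that prompted the idea and replaced an earlier test of it after results were seen. If instead the deposited value averages a female and a male fold change, Y-linked genes could keep small averages despite small adjusted p-values. All 4 lay inside the edge of the falls, Ddx3y barely, against 1 of 1722 other lower genes (Fisher's exact test, p = 1.36e-11), but the idea came from these same genes, so the test lends it no support, and 8 higher genes that are not sex-linked, such as Atf3 and Cebpb, lay inside the edges too. The averaging reading stays open, as does a difference between females and males in their response, which was not tested.

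The atrial-type genes Sln, Myl7 and Mybphl were among the 4 largest falls. Less atrial tissue in the treated samples was tested on the separate list of atrial and conduction markers, of which 4 of 8 were lower (Fisher's exact test, p = 0.736); the list includes genes that other heart cells express, such as Clu, Pam and Tbx18, so it does not settle the point. Atrial carry-over in some control libraries only may give large averages with weak adjusted p-values, and these 3 genes ranked at percentile 95.9 or beyond, toward the weakest, among the 121 genes with an absolute log2 fold change of 3 or more. Against that, Sbk3 and Sbk2 of the atrial list fell by 2.46 and 2.28 with adjusted p-values of 5.78e-25 and 1.10e-39 in the authors' deposited table, and the ranking was made on the genes that prompted the idea, so it stays open. A low level in ventricle would also weaken p-values, levels were not analysed here, and an effect of AngII/PE on these genes in ventricular muscle was not tested.

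Fatty acid oxidation and respiratory chain genes fell together. A lower share of heart muscle cell RNA, with the other cell types in their old proportions, would raise the markers of those types alike. Macrophage markers were higher in 18 of 18 and endothelial and Schwann markers lower in 16 of 19 listed genes (Fisher's exact test, p = 8.71e-08). These directions were known when the prediction was written, so the p-value adds nothing. Rises short of 0.59 were mostly not listed, and 12 of 25 endothelial and 3 of 9 Schwann genes had no value analysed here. Part of the endothelial lean (median -0.53) can therefore come from the listing. The falls of the listed endothelial and Schwann genes argue against this explanation for those genes alone, as far as they are specific to their cell types. Dilution by fibroblast and macrophage RNA could lower the metabolic, endothelial and Schwann genes alike and stays open. Medians of listed genes were -0.91 for contraction and calcium handling and -0.83 for fatty acid oxidation (difference -0.081, permutation p = 0.512). In a comparison first meant to test dilution, the median was -0.62 for oxidative phosphorylation (fatty acid oxidation lower by a difference of -0.21, permutation p = 3.00e-05). Small changes are not listed and 44.0% of the contraction list has a value, so these comparisons decide nothing. The 14 contraction genes without a value include Ttn, Actn2 and Tnnt2, although falls beyond -0.38 could be listed. A dilution alike for all heart muscle genes, as large as those medians, could be expected to list more of them. The rule of listing is not given, so their absence does not settle the point. Length was taken from the longest annotated transcript of each gene, which need not be the one expressed. By that measure, loss of short transcripts in the treated libraries is argued against for the fatty acid oxidation genes. Of 1012 other protein coding genes in their interquartile range of length (2168 to 3740 bases), 65.7% were higher (95% exact binomial interval 62.7% to 68.6%). That test was added after the other results were seen. For the shorter respiratory chain genes such a loss cannot be told apart, with 52.0% of 196 other short genes higher (44.8% to 59.2%) against 63.8% of 2933 longer genes (Fisher's exact test, p = 0.00128), and an effect of AngII/PE within heart muscle cells was not tested.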
